A study of Chrysanthemum x morifolium with 6 samples.

How the data were processed

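Leaves of the chrysanthemum cultivar Jinba (Chrysanthemum x morifolium) were profiled by short-read RNA sequencing in 6 libraries, 3 from control plants and 3 from plants exposed to cold. Per the labels' protocols, RNA was extracted with Trizol and short-read libraries were prepared with an Illumina TruSeq kit; a full-length cDNA (Iso-Seq) library is described as well and was not analysed here. The submitters' processing notes name Bowtie2 2.0.6 and TopHat2 2.0.12 without giving their role. The reference that reads were aligned to, the counting program, the way the features were built and any filter are not given in the sources used here.

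The authors deposited one table of FPKM values (fragments per kilobase of feature, scaled to the mapped fragments of each library), rounded to 2 decimals, for 365669 features in the 6 libraries. Each feature name, such as Cluster-2961.23449, holds a first and a second number. The first is read here as the number of a component and the second as a number within that component. The file pairs no feature with a gene name, a sequence, a length or a genomic position. No reference genome or table of names was used here. The gene lists that had been fixed before the data were examined (cold-response, photosynthesis, hormone, cell wall, clock and cell type lists, each found by words in gene names) could therefore not be applied, and no list has a result. The largest component holds 299531 features (81.9%); the next largest holds 23. Features of this kind can split or share the reads of near-identical gene copies, so each single-feature value is uncertain in that respect.

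The FPKM file gives no counts, so absolute depth is unknown and no counting interval was computed. Relative depth could be read from the steps between low values. For features above 0 in exactly 2 libraries, the commonest ratio of the values (within 0.03 on the log2 scale) was taken as the ratio of what 1 fragment is worth. On simulated whole fragments this recovered the true depths with a largest error of 8.3e-05. The simulated features had whole counts and a fixed length, so this error does not carry over to the real values. With control 1 set to 1, the relative depths were 0.74 for control 2, 0.86 for control 3, 0.91 for cold 1, 0.85 for cold 2 and 0.91 for cold 3. Each estimate rested on between 72 and 206 features at the commonest ratio. These were 22.8% (control 2) to 42.4% (cold 2) of the features used.

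The FPKM values were used as deposited. Features with a mean FPKM over the 6 libraries of at least 1 were kept (153984), transformed as log2(FPKM + 1) and compared between cold and control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, no block, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are on the log2(FPKM + 1) scale, which understates the change of features near 0. Called features are those with an adjusted p under 0.05. The features named by number were the 2 with the largest rise and the 2 with the largest fall among called features with no overlap between the groups and a mean FPKM of at least 5 in the higher group, a rule fixed before the data were examined for the case that no gene names were given. The features that are most abundant in each group were singled out after their values were seen.

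The design was tested on simulated data drawn from the real means and spreads of all 153984 features. The changed features were drawn only from those with a mean of at least 5 FPKM, which 55072 tested features reach. The recovery rates therefore do not cover features between 1 and 5 FPKM, where the spread between libraries is larger. With 200 features changed, the test recovered 5 of 50 rises of 2-fold, 29 of 50 rises of 4-fold, 5 of 50 falls to 0.5 and 10 of 50 falls to 0.25, with 5 of 54 calls false. With 20000 features changed, closer to the number called here, it recovered 64.5% of the 2-fold rises, 86.1% of the 4-fold rises, 58.7% of the falls to 0.5 and 80.8% of the falls to 0.25, and 5.34% of calls were false. Counts of calls therefore leave out part of the 2-fold changes. The simulated noise was independent between features and held no difference in scaling between libraries. The rates of false calls therefore leave out any calls that such a difference makes in the real data.

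Pairs of libraries were compared by Pearson's r over features, which are not independent replicates, and by principal components. Library totals were compared by a two-sided exact permutation test over the 6 libraries, whose smallest possible p is 0.1. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, 3 other scalings of the libraries (median of ratios, a sum of 1000000 per library, quantile normalization), limma without trend or with robust empirical Bayes, a log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. The sum of 1000000 also lowers every value 2.61-fold on average against the fixed pseudocount of 1, so equal sums at the mean level of the 6 libraries were added after seeing the data. The labels do not say that a shared replicate number marks a shared plant, day or batch, so the block was not part of the design.

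The series' design text describes pooling leaves from 3 replicates for each treatment and speaks of 2 samples in total for sequencing, while 6 libraries are labelled, 3 per treatment. Whether the 3 libraries of a treatment come from separate plants cannot be read from this, so the p-values measure the spread between these libraries, which may be technical. No pair of libraries was a duplicate: of features at 10 FPKM or more in both, at most 0.113% held identical values in any pair. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.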

Results

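Transcript levels were measured in leaves of young chrysanthemum plants under 2 conditions. Tissue-cultured plants were raised for 30 days on medium under a 16 h photoperiod (25 °C by day, 22 °C by night), potted and given 5 days to settle. Control leaves came from plants left in normal conditions. Cold leaves came from plants held at 4 °C for 24 h and then at -4 °C for 4 h, a chilling followed by a subzero exposure. Each condition has 3 libraries. The single comparison in the design, cold against control, asks which transcripts differ in leaves after chilling and freezing. Both exposures are combined, so their separate contributions cannot be read from these libraries.

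The 6 libraries fell into their 2 labelled groups. Pearson's r of log2(FPKM + 1) over the 153984 tested features averaged 0.84 among control libraries and 0.86 among cold libraries. Between a control and a cold library, r lay between 0.66 and 0.67. The first principal component held 54.7% of the variance and separated the 3 cold libraries from the 3 control libraries, and the second held 12.1% and spread mainly the control libraries. Feature-level FPKM sums were 2615325, 2648484 and 2631598 for control 1 to 3 and 2577065, 2589509 and 2588629 for cold 1 to 3. The relative depths of the cold libraries, 0.85 to 0.91 of control 1, lay inside the range of the control libraries, 0.74 to 1.

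**Figure D1:**
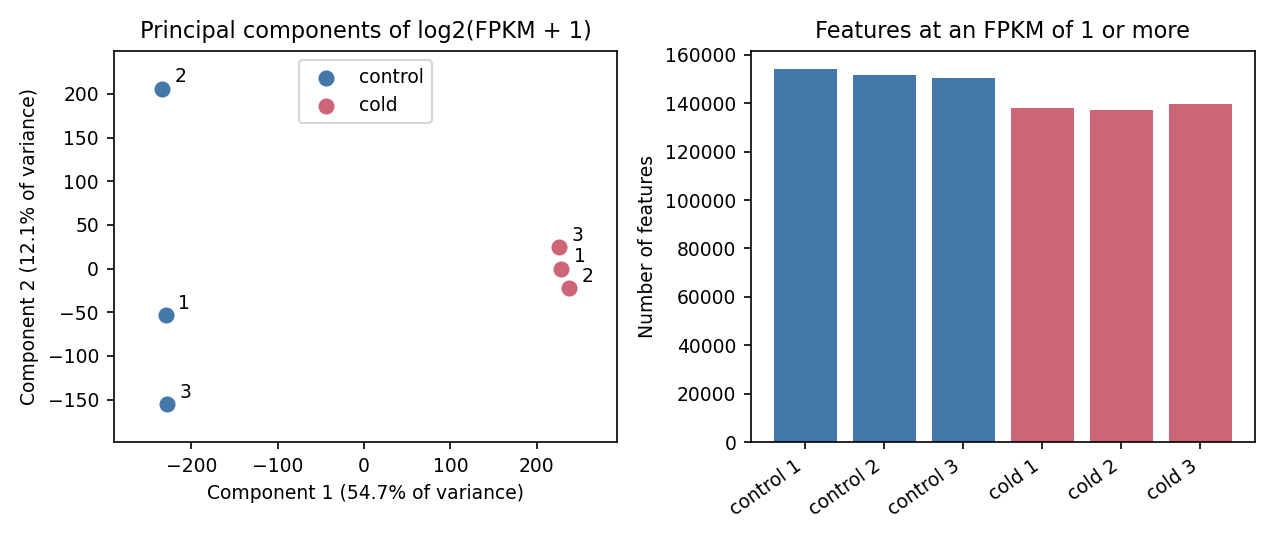
Left, the first 2 principal components of log2(FPKM + 1), in arbitrary units, with 1 point per library labelled by its replicate number and coloured by group (control blue, cold red). Right, the number of features at an FPKM of 1 or more in each library, as bars from 0. The cold libraries stand apart on component 1, and each holds fewer such features (137238 to 139502) than any control library (150553 to 153982).

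Fewer features were above a low level in cold than in control leaves. On average 152013 ± 1770 features reached an FPKM of 1 in control libraries and 138319 ± 1135 in cold libraries (SD, n = 3 each). The difference of 13694 features was larger than the spread within either group. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 can give. At an FPKM of 10 or more the numbers were 33047 ± 316 and 31818 ± 59.2, again with no overlap and p = 0.1 by the same exact permutation test. The number of features with any value above 0 was 252392 to 259834 in control and 243710 to 252195 in cold libraries, which lie close to each other without overlap (p = 0.1 by the same exact permutation test). Rescaling the libraries by the median of ratios narrowed the gap at an FPKM of 1 to 42.2% of its size, and the groups still did not overlap.

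Levels differed between cold and control leaves for 35.6% of tested features. Of the 153984 features, 24366 were higher and 30500 were lower in cold than in control leaves, and the other features did not pass the test (limma, adjusted p under 0.05). The test measures the spread between these libraries, which may be technical. The share called depended on the filter. Without a filter 25394 were higher and 31930 lower of 344438 features, and at a mean of 5 FPKM 14850 and 15843 of 55072. The change was at least 2-fold (1 on the log2 scale) for 16315 of the higher and 21115 of the lower features, and at least 4 on the log2 scale for 491 and 291. All 3 cold libraries lay above all 3 control libraries for 33674 features and below them for 43365, together 50.03% of tested features. For a single feature with exchangeable libraries the chance of this is 10%. All features share the same 6 libraries, and a difference in scaling between the groups would also separate features. The share was counted on the deposited values only, so 10% is not a chance level for it. Features called higher took 15.6% ± 0.0727 of the FPKM total in control libraries and 41.0% ± 0.199 in cold libraries. Features called lower took 51.4% ± 0.169 in control and 26.8% ± 0.170 in cold libraries (SD, n = 3 each). Both sets were chosen on these same libraries, so their directions are not independent evidence.

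Which direction was in the majority depended on the scaling between libraries. As deposited, 55.6% of called features were lower in cold, and the median log2 fold change of all tested features was -0.13. With the libraries rescaled by the median of ratios, 28843 features were higher and 25464 lower, so that 46.9% were lower. Quantile normalization gave 49.3% lower. Rescaling each library to a sum of 1000000 gave 54.2% lower.

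The 100 most abundant features were mostly lower in cold, and the 1000 most abundant were not. Of the 100 features with the highest mean FPKM over all libraries, 70 were called lower, 21 higher and 9 did not pass the test (limma). Their median log2 fold change was -0.45, or -0.32 relative to the median of all features. It was -0.28 with the median of ratios, -0.42 with a sum of 1000000 and -0.16 with quantile normalization, which is -0.13 relative to all features. More of these 100 features were called lower than higher under all 3 other scalings, at 64 against 26 (median of ratios), 69 against 21 (sum of 1000000) and 50 against 31 (quantile normalization). Of the 1000 most abundant features, 413 were called higher and 407 lower, with a median log2 fold change of -0.0031. That balance moved with the scaling, to 481 higher against 315 lower with a median of 0.16 (median of ratios), 419 against 395 (sum of 1000000) and 368 against 465 (quantile normalization). Together these 100 took 20.9% ± 0.252 of the FPKM total in control libraries and 17.9% ± 0.195 in cold libraries (SD, n = 3 each). The feature most abundant in control leaves had 25616 ± 1753 FPKM there and 17525 ± 399 FPKM in cold leaves, a log2 fold change of -0.55 ± 0.048 (SE; limma adjusted p = 0.00049). That feature was lower in cold under each scaling, by -0.38 to -0.84 on the log2 scale.

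Of the 21 features among the top 100 that were called higher, 1 became the most abundant of the cold leaf. It rose from 632 ± 56.6 FPKM in control to 51825 ± 7490 FPKM in cold libraries (SD, n = 3 each), which is 82.0-fold. On the log2 scale the change was 6.35 ± 0.12 (SE; limma adjusted p = 2.64e-06), and it ranged from 5.78 to 6.52 over the other scalings. It ranked 304 among features in control libraries and 1 in cold libraries. Its share of the FPKM total went from 0.0240% ± 0.00227 to 2.00% ± 0.285. The file gives no gene name for it.

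By abundance class, the share of features called rose with the mean FPKM. It was 29.4% of the 122083 features between 1 and 10 FPKM, 57.1% of the 28493 between 10 and 100, 77.8% of the 3236 between 100 and 1000, and 89.5% of the 172 at 1000 or more (limma). The spread between libraries was smaller at high abundance. The median coefficient of variation among control libraries was 43.6% at 1 to 3 FPKM, 13.8% at 10 to 30 and 4.52% at 1000 or more. Among cold libraries it was 43.8%, 12.8% and 2.62%. In the lowest class 14917 features were higher and 21012 lower. In the class from 10 to 100 these numbers were 8041 and 8226, and in the class from 100 to 1000 they were 1360 and 1156. At 1000 FPKM or more, 48 were higher and 106 lower. The class at 1000 or more kept its majority under the 3 other scalings, with 61.6% (median of ratios), 68.2% (sum of 1000000) and 62.5% (quantile normalization) of its called features lower. The other 3 classes changed sides under at least 1 scaling. Quantile normalization gave 48.5% lower from 1 to 10 FPKM and 53.3% lower from 100 to 1000 FPKM, and the median of ratios gave 41.5% lower from 10 to 100 FPKM.

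**Figure D2:**
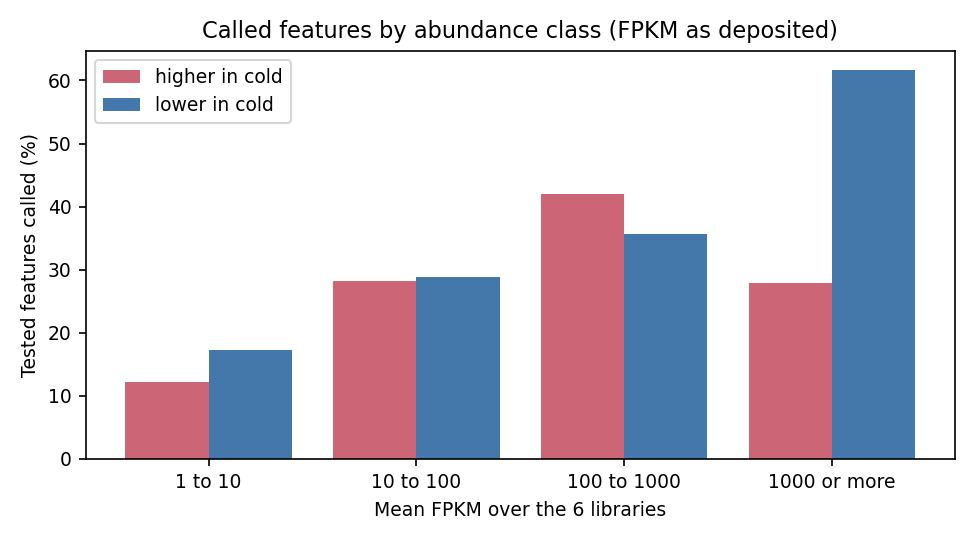
Percent of tested features called higher (red) or lower (blue) in cold by limma at an adjusted p under 0.05, by class of mean FPKM over the 6 libraries, with FPKM as deposited. The total called rises from 29.4% in the class from 1 to 10 FPKM to 89.5% at 1000 or more, where 106 features were lower and 48 higher.

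The 2 features with the largest rises went from near absence to high abundance. Cluster-2961.23449 had 1.46, 0.34 and 0.99 FPKM in the control libraries and 1205, 1167 and 1172 FPKM in the cold libraries. Its log2 fold change was 9.30 ± 0.22 (SE; limma adjusted p = 4.7e-06), and its size depended on the level of the values against the pseudocount. It was 8.41 with a sum of 1000000, which lowers all values 2.61-fold on average, and 10.35 with a pseudocount of 0.1, but 9.32 with equal sums at the deposited level. Cluster-2961.277240 was listed at 0 in control 1 and 3 and at 2.4 FPKM in control 2, and had 865, 884 and 838 FPKM in the cold libraries. Its log2 fold change was 9.17 ± 0.48 (SE; limma adjusted p = 6.78e-05). It was 9.75 without control 2, the only control library with a value, 8.08 with a sum of 1000000, 11.53 with a pseudocount of 0.1, and 9.18 with equal sums at the deposited level. These were chosen from 17189 features that met the other conditions of the naming rule in this direction.

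The 2 features with the largest falls were well expressed in control leaves and listed at 0 in all 3 cold libraries. Cluster-2961.146410 had 225, 294 and 265 FPKM in control 1 to 3 (limma adjusted p = 1.75e-06). Cluster-2961.160414 had 222, 137 and 156 FPKM in the same libraries (limma adjusted p = 6.35e-06). No fold is given for either, because a fold against 0 depends on the pseudocount. These came from 19242 features that met the other conditions in this direction. Neither a gene name nor a genomic position is given in the file for any of the 4.

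**Figure D3:**
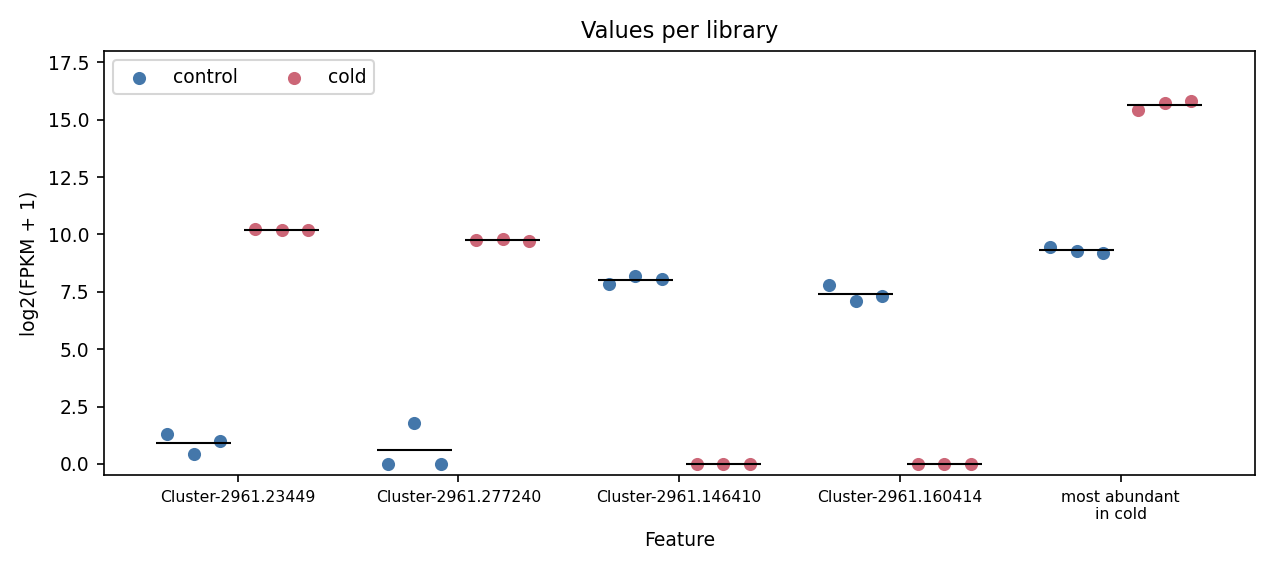
Values per library as log2(FPKM + 1) for the 2 features with the largest rises, the 2 with the largest falls and the most abundant feature of the cold libraries. Each point is 1 library (control blue, cold red) and black lines are group means; the 2 features that fell sit at 0 in all 3 cold libraries, and the most abundant one moves by 6.35.

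Some features had values in only 1 of the 2 conditions. In 2058 features all 3 cold libraries were at 1 FPKM or more and all 3 control libraries were listed at 0, and 249 of them averaged at least 10 FPKM in cold. The reverse held for 2323 features, of which 217 averaged at least 10 FPKM in control. The sum, 4381, compares with at most 621 such features when the 6 libraries were split into 3 and 3 in any other way. Those splits mix both conditions on each side, so 621 is not a chance level. A listed 0 is not proof of absence in this table. Among features at 10 FPKM or more in 2 control libraries, 700 of 31900 (2.19%) were listed at 0 in the third, and among cold libraries 675 of 30733 (2.20%).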

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

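The alternatives fixed beforehand left the counts of higher and lower features within 1.5 times of 24366 and 30500, except the filter at a mean of 5 FPKM, which tests 55072 features and called 14850 higher and 15843 lower. The direction of the majority changed under 2 scalings: the share of called features that were lower was 46.9% with the median of ratios and 49.3% with quantile normalization, against 55.6% as deposited. Leaving out 1 library gave 18718 to 21442 higher and 22389 to 25511 lower features, and 51.7% to 57.7% lower. With the replicate number as a block, 19061 features were higher and 23058 lower, and 40547 of the 54866 calls were kept in the same direction. The deviations of same-numbered libraries from their group means correlated at -0.0022, -0.0061 and -0.012. For differently numbered libraries the values were -0.0025 to 0.0087. No pairing by number showed over the features as a whole. A shared plant, day or batch that acts on few features would not be seen in this way. The 4 named features kept their direction and stayed under an adjusted p of 0.05 (limma) in all of these alternatives, other than the fold threshold, in which they were not refitted; the highest value was 0.0018, under the block. The sizes of their changes moved with the level of the values against the pseudocount, which the sum of 1000000 also changes. Equal sums at the mean level, added after seeing the data, gave 25026 higher and 29619 lower features. Mean correlations within groups (0.85) and between groups (0.67) moved with settings chosen after seeing the data, to 0.73 and 0.51 with a pseudocount of 0.1, 0.82 and 0.62 with 0.5, 0.88 and 0.76 without a filter, and 0.87 and 0.57 at a mean of 5 FPKM or more; within stayed above between in each. Also chosen after seeing the data, the threshold for features with values in 1 condition moved their number to 3738 (cold) and 4638 (control) at 0.5 FPKM and to 368 and 295 at 5 FPKM. Without 1 library there were 3039 to 3341 cold-only and 3556 to 3956 control-only features, an increase that follows from requiring fewer libraries. The set tests of gene lists and the count of 1 feature per gene name were not run, because the features carry no names. FPKM do not give the depth, so the counting error of single features cannot be set apart from their other spread.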

Other observations

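The tests of depth, of the share of the most abundant features and of scaling on the number of detected features were chosen after the values were seen, and the other tests below before the result they measure.

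Features of one component changed together. Outside the largest component, 663 components held at least 2 tested features, and the log2 fold changes of their 2 most abundant members had a Spearman's rho of 0.60 across components. In 1000 shuffles among pairs of like abundance rho lay between -0.11 and 0.17 (permutation p = 0.001, the smallest they can give). Of 65 pairs with both members called, 64 changed in the same direction, where the margins alone give 70.9%. The deviations of paired members from their group means had a mean rho of -0.020 over the 6 libraries, which argues against noise shared within single libraries. Members may be pieces of one transcript, or copies of one gene that respond alike in this polyploid plant; no sequence was at hand to tell these apart, and no biological explanation was tested.

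The numbering inside the largest component carried a weaker trace of the same kind. Over 49958 pairs of tested features with consecutive numbers, the log2 fold changes had a rho of 0.25, above all 1000 shuffles among features of like abundance, whose highest value was 0.026 (permutation p = 0.001, the smallest they can give). Of 8583 pairs with both members called, 6193 (72.2%) changed in the same direction, where the margins give 50.5%. What the numbering stands for is not given in the sources used here. Changed features are thus not independent of each other.

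Fewer features reached an FPKM of 1 in cold libraries. Lower depth is argued against by control 2, which had the lowest estimated relative depth of all 6 libraries (0.74). It had 151504 such features, more than the 139502 of the highest cold library. A larger share of the FPKM total taken by the 100 most abundant features is argued against by the shares themselves. The 100 most abundant features of each library took 18.3% to 18.7% of the FPKM total in cold and 21.5% to 22.0% in control libraries. The 10 most abundant took 6.60% to 7.09% in cold and 7.10% to 7.25% in control libraries, ranges that nearly touch. The single most abundant feature took more in cold (2.00% on average) than in control libraries (0.973%). Larger sets of each library were not compared. Rescaling by the median of ratios left 42.2% of the gap with no overlap between the groups, so that scaling stays open for it, with the cold exposure itself among the untested explanations. Scaling also stays open for the majority of lower over higher calls. It was gone under the median of ratios, with 46.9% of calls lower, but that scaling centres the fold changes (their median went from -0.13 to -0.011), so the loss does not tell a scaling effect from an excess of features that fell.

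Chance in the grouping of libraries cannot be tested at the 0.05 level with 10 splits of 6 libraries into 3 and 3. The real split called 54866 features, 1 of the 10 splits reached that number, and the highest of the others called 3. Every other split mixes cold and control libraries on both sides, which widens the spread within its sets. Few calls there are built in, so 3 is not a chance level.

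The spread between libraries at high abundance was set against limits fixed beforehand for counting noise alone. The median coefficient of variation at 1000 FPKM or more was 0.33 of that at 10 to 30 FPKM among control libraries (95% bootstrap range over features 0.299 to 0.363) and 0.21 among cold libraries (0.164 to 0.227). The values set beforehand were at most 0.2 for counting noise and over 0.3 against it. They were set for the ratio and not for its bootstrap range. The control ratio of 0.33 was over 0.3, and the cold ratio of 0.21 lay between the limits and decided nothing. The control range lies wholly above 0.2, which argues against counting noise alone among control libraries, but its lower end falls short of 0.3. Their median was 4.55% at 300 to 1000 FPKM and 4.52% at 1000 or more. Among cold libraries the range takes in 0.2, and the median went from 3.16% to 2.62% between the same classes. The unknown absolute depth cancels in this ratio, but the lengths of the features, which also set their counts, are not given.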
